A study of Mus musculus with 25 samples.

How the data were processed

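RNA was measured in a random section of whole lung from male C57BL/6 x CBA F1 mice that lived in a shed in Hamilton, either in ambient urban air or in a plexiglass unit with HEPA-filtered air. Kind of air and housing went together, so the comparisons cannot tell them apart. Below, an effect of ambient air means a difference between these arms, housing included. Mice housed together are not independent replicates of the air, which an SE or p over mice does not take into account. Per the labels, mice were sampled after 3 weeks, after 10 weeks, or at week 16, which was 10 weeks of exposure and 6 weeks of recovery in an animal facility. Lung RNA carried Cy5 and Universal Mouse Reference RNA carried Cy3 on every array, so the dyes were never swapped and any dye effect of a gene was shared by all groups.

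The deposited data are 50 scanner files, 1 per channel of 25 arrays, and 1 series matrix. Per the file headers, the scanner files hold spot intensity, on a linear scale up to 65535 and without background subtraction, beside spot flag codes and a mark for saturated spots. The series matrix was made by the authors and holds log2 ratios of lung over reference, which was checked against the scanner files. Its values followed the unsubtracted log2 ratio of the same array with r between 0.902 and 0.997 and slopes between 0.804 and 0.991 across probes, and its medians lay between -0.04 and 0.02. The background subtraction, the loess settings and the averaging of repeated spots behind it are not given in the sources used here, so the scanner files were the starting point and the series matrix was 1 of the alternatives. The design text names Agilent Feature Extraction 9.5.3.1, but the columns of the deposited scanner files are not those of that program, so the program that quantified the spots is unknown.

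Samples were grouped by their labels alone: 4 filtered and 5 ambient at week 3, 4 filtered and 7 ambient at week 10, 4 filtered and 1 ambient at week 16. The design text gives 5 mice per group and 30 in all, against 25 arrays here. Samples 45, 49, 53 and 57 are labelled ambient week 10 but carry numbers above those of the other week 10 samples, from 34 to 42, and beside or among those of the week 16 samples, from 46 to 61, so their week is in doubt. They stayed as labelled. Gene counts, gene values and list tests were also computed without them. Regroupings of the samples, tests of explanations and correlations across genes were not. The file headers of filtered week 3 sample 2 name sample 8, and it also stayed as labelled. The files give no slide and no scan date. Numbers in the file headers fell into 7 batches when parted at gaps over 1000 and into 3 coarser ones at gaps over 10000. Weeks 3 and 10 each had 4 of the 7 batches with both kinds of air.

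Each array held 22575 spots, of which 1257 control and unnamed spots were left out, and repeated spots of a probe were averaged. This left 20868 probes: 18303 with 1 gene symbol, 0 with several and 2565 with none, covering 16966 genes. Of the named probes, 18134 matched an Entrez number. The median signal of both channels was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log2 ratios were adjusted by loess within each array, with no scaling between arrays. A probe was kept when its Cy5 signal exceeded the local background by more than 2 background SD on at least 4 of the 25 arrays, which 19168 probes did. Among probes of 1 gene, the probe with the highest mean brightness stood for it, which gave 15841 genes.

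All 25 arrays entered 1 limma fit (lmFit and eBayes) with a mean for each of the 6 groups and a shared spread, so the lone ambient week 16 sample was assumed to vary like the other groups. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 within a comparison. Counts at an unadjusted p under 0.05 are given as well, and chance alone gives a share of about 0.05 of the genes tested there. Errors of log2 differences are the SE of that fit. The comparisons were ambient over filtered air at weeks 3, 10 and 16, the mean of the week 3 and week 10 effects, the difference between those 2 effects, and weeks 10 over 3 and 16 over 10 within filtered air. Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 39 lists within a comparison, with an estimated correlation and with fry beside it. The count of members called "adjusted over the list alone" stands beside the count over all genes. Groups, comparisons, filter, tests, the 39 lists, the naming rule and most alternatives were chosen before the data were examined.

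Named genes were, for the ambient air comparisons at weeks 3 and 10 and the comparisons built on both, the 10 largest called rises and the 10 largest called falls. For week 16 and for the comparisons within filtered air they were 5 and 5. Where fewer than 5 genes were called, the 10 with the smallest p were named with their values alone. Up to 4 members of each list with the smallest p, and always Plin1, Plin2, Plin4, Cidea, Cidec, Dgat1, Dgat2, Adipoq, Ucp1, Cyp1a1, Hmox1 and Saa3, were also open to naming. Clone names stayed in the counts and out of the naming. A list of 31 markers of keratinized squamous epithelium was written after the data were seen, 14 of them because they had been seen to differ, and it is kept apart from the 39.

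The method was tested on simulated data in which 200 genes were changed. For changes of 1 on the log2 scale it recovered 42% of genes at week 3, 58% at week 10, 55% for week 16 over 10 in filtered air and 10% at week 16. For changes of 2 it recovered 91%, 94%, 92% and 54%, with 11, 12, 19 and 6 false calls. In each of these single simulations the false calls were a larger share of all calls than the threshold of 0.05 aims at. The simulated noise was independent from gene to gene, without shifts shared by many genes of an array, so rates on real arrays may differ. On real arrays, precision is limited by the number of arrays, the signal over background and saturation.

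The alternatives were no background subtraction, an offset of 16, Aquantile scaling, the Cy5 channel alone, the series matrix, no filter, a filter on all 25 arrays, all probes apart, the Cy5 scanner gain as a covariate, eBayes with trend and robust, array weights, the compared arrays alone, the arrays without the 4 samples in doubt or with those alone, each sample left out, and an unadjusted p under 0.05 with at least a 1.5-fold change. Further alternatives were added after the data were seen: the batch as a fixed or a random block, the coarser batch as a fixed block, Signal Mean, poor spots left out, and arrays with over 25% of negative controls detected left out. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.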

Results

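Gene expression was measured in the lungs of 25 mice, 1 array per mouse, that breathed ambient urban air or the same air after HEPA filtration. Week 3 held 5 ambient and 4 filtered samples, week 10 held 7 and 4, and week 16, after 6 weeks of recovery in an animal facility, held 1 and 4. Between 49.5% and 94.7% of probes were detected per array (median 65.0%), and between 0.311% and 4.37% of probes were saturated in the Cy5 channel. Negative control spots, which match no mouse gene, were detected at a median of 3.70%, with a highest value of 72.2% in filtered week 10 sample 42. Detection counts below include that array, so a gene counted as detected there may lie near background. Expression is the log2 ratio of lung over a common reference RNA, differences are given with the SE of the fit, and 15841 genes were tested. No alternative setting moved the median difference of all genes by more than 0.1 at weeks 3 or 10.

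The first question was how the lung differed between ambient and filtered air after 3 weeks. Markers of skeletal muscle, brown fat and white fat were higher in ambient air (n = 5) than in filtered air (n = 4). Elovl3 (probe A_51_P324636), a fatty acid elongase typical of brown fat and skin, was called higher (adjusted p = 0.0200). It was detected on 1 of 4 filtered and 5 of 5 ambient arrays, so its level in filtered air lay near background and no size is given. Ly6d (probe A_51_P343517), a surface protein of squamous epithelium and early B cells, rose by 1.98 ± 0.34 on the log2 scale, 3.95-fold (adjusted p = 0.0434). Immediate early genes, which respond to stimuli within minutes, fell as a group by a median of -0.37.

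These 2 rises and 0 falls were all the genes called at week 3, while 1303 genes had an unadjusted p under 0.05 in limma, 855 of them higher in ambient air. Among the genes with the smallest p, the muscle enzymes Pgam2 and Eno3 differed by 2.22 ± 0.42 and 2.23 ± 0.43. Cpt1b, the muscle and brown fat carrier of fatty acids into mitochondria, differed by 2.30 ± 0.44, and the tubulin Tuba8 by 1.37 ± 0.26, each at an adjusted p of 0.0557. Ccdc96 differed by -1.45 ± 0.28 at the same adjusted p, and Dgat2 by 2.49 ± 0.49 (adjusted p = 0.0698). Olfr135 and Fat3, also among them, were detected on 1 of 4 filtered arrays and on 0 and 1 of 5 ambient arrays, so no size is given.

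The skeletal muscle list rose (median 2.20, camera adjusted p = 3.48e-17, and adjusted p = 0.0254 with an estimated correlation). Of its 18 measured genes, 17 were higher, 0 were called over all genes and 15 adjusted over the list alone. Only 8 of the 18 were detected on all 8 filtered arrays of weeks 3 and 10. Myl1, a fast muscle myosin light chain, differed by 3.23 ± 0.67 (adjusted p = 0.0742). The brown adipocyte list rose by a median of 1.17 (camera adjusted p = 6e-15; adjusted p = 0.00927 with an estimated correlation), with 17 of 19 genes higher, 1 called and 14 adjusted over the list alone. Ucp1, the uncoupling protein that makes heat in brown fat, went from -0.33 (SD 0.70) to 4.71 (SD 1.42), a difference of 5.04 ± 1.15 that was not called (adjusted p = 0.113). It was detected on 2 of 4 filtered arrays, so the size of that difference is uncertain. White adipocyte markers rose by a median of 1.15 (camera adjusted p = 1.11e-10; adjusted p = 0.0254 with an estimated correlation), with 14 of 16 higher and 7 adjusted over the list alone. The list means were higher in ambient air in each of the 4 batches that held both kinds of air, on average by 1.78 (0.45 to 3.56) for skeletal muscle, 1.21 (1.03 to 1.35) for brown fat and 0.97 (0.45 to 1.45) for white fat. The skeletal muscle mean of ambient sample 5 was -1.28 and that of filtered sample 2 was 0.23, each inside the range of the other kind of air.

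The lipid droplet list, which follows the study title and so is not independent of these samples, rose at week 3 by a median of 0.50 (camera adjusted p = 2.89e-08; adjusted p = 0.0626 with an estimated correlation). Of its 25 measured genes, 23 were higher, 0 were called and 9 adjusted over the list alone. It shares 4 genes with the adipocyte lists, and without those its camera adjusted p was 4.18e-05. Its median was 0.33 without ambient sample 7. Plin4, which coats adipocyte droplets, differed by 1.97 ± 0.42 (adjusted p = 0.0742), and Agpat2, an enzyme of triglyceride synthesis, by 1.72 ± 0.47 (adjusted p = 0.189). Plin2, the droplet coat protein of most other cells, differed by 0.36 ± 0.29 (adjusted p = 0.825) and Dgat1, which adds the last fatty acid to triglyceride, by 0.50 ± 0.31 (adjusted p = 0.731). Plin1, Cidea, Cidec and Adipoq, all genes of adipocytes, differed by 2.23 ± 0.71, 2.04 ± 0.78, 1.52 ± 0.55 and 1.68 ± 0.60, with adjusted p from 0.309 to 0.455. Within the 4 batches the droplet list mean was higher in ambient air by 0.36 to 0.78, in arrays where the adipocyte markers were also higher.

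Respiratory chain genes rose together, all 24 higher with a median of 0.66 (camera adjusted p = 7.25e-16; adjusted p = 0.0769 with an estimated correlation) and 12 adjusted over the list alone. Fatty acid oxidation genes (median 0.76), cardiac muscle markers (1.09) and fatty acid synthesis genes (0.40) also rose by camera, with adjusted p of 0.0769, 0.0626 and 0.198 with an estimated correlation. B cell markers rose by a median of 0.48 (camera adjusted p = 4.86e-05; adjusted p = 0.103 with an estimated correlation), and within the 4 batches their mean was higher by 0.60 on average. Smooth muscle and thymus markers rose by medians of 0.30 and 0.51 (adjusted p = 0.321 and 0.344 with an estimated correlation). The fall of immediate early genes had a camera adjusted p of 3.36e-05 (adjusted p = 0.0254 with an estimated correlation), 14 of 17 genes were lower and 5 fell adjusted over the list alone. Jun and Btg2, of this list, differed by -0.59 ± 0.16 and -0.57 ± 0.17. Neutrophil markers and interferon response genes fell by medians of -0.33 and -0.17, calls lost with an estimated correlation (adjusted p = 0.296 and 0.344). Medians that moved over 1.5 times were 0.13 for smooth muscle without filtered sample 2, -0.11 for interferon and -0.20 for neutrophils without filtered sample 6, and 0.21 for fatty acid synthesis without ambient sample 7. Alveolar type 2 cell markers had a median of -0.18 and a mean of 0.03 and were not called (camera adjusted p = 0.926). Pollutant response genes were not called: aryl hydrocarbon receptor targets had a median of 0.23 and a mean of -0.05 (camera adjusted p = 0.73), NRF2 oxidative stress targets a median of -0.05 (0.73) and inflammatory cytokines a median of 0.04 (0.723). Cyp1a1, the classic target of combustion hydrocarbons, differed by -0.94 ± 0.64 (adjusted p = 0.772), Hmox1 by -0.18 ± 0.22 (0.908) and Saa3 by -0.17 ± 0.53 (0.975).

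Squamous epithelium markers, a list written after the data were seen, had a median of 1.09 at week 3 with 23 of 28 higher and 1 called (Ly6d), while its 14 members not seen beforehand had a median of 0.12. The median of all 28 was 0.69 without ambient sample 9.

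The 2 calls of week 3 rested on single samples and on the setting: leaving out 1 sample gave between 0 and 34 genes, with 34 without filtered sample 2, 24 without ambient sample 5, 21 without ambient sample 1, 1 without ambient sample 9 and 0 without filtered samples 4 or 10 or ambient samples 3 or 7. With the batch as a fixed block 2 genes were called, 0 of them shared, and 0 were called by limma with the coarser batch as a block, with the Cy5 scanner gain as a covariate, or from the week 3 arrays alone (1247, 1375 and 1316 at an unadjusted p under 0.05).

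**Figure D1:**
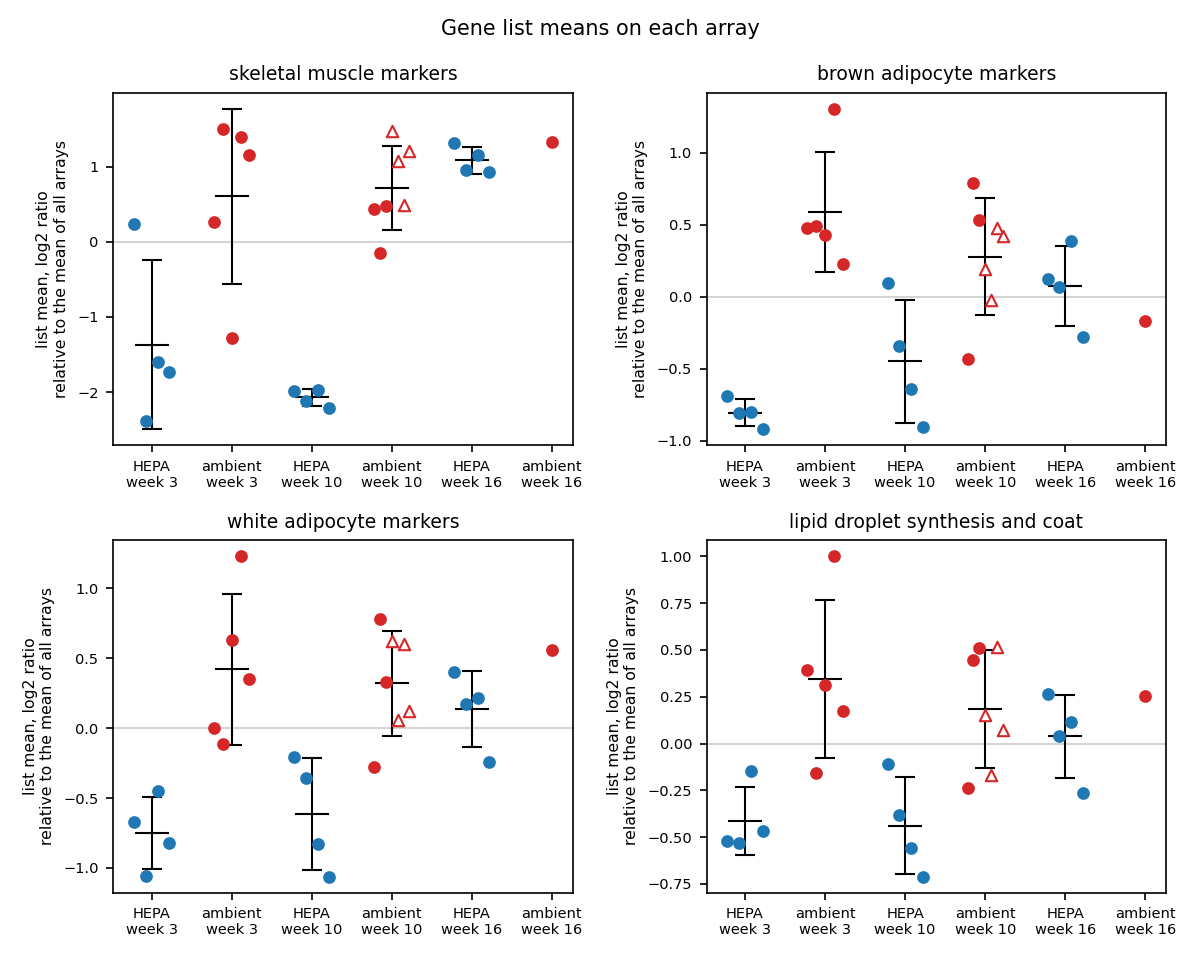
Mean log2 expression of the genes of each list, relative to their mean over all arrays, for skeletal muscle, brown adipocyte, white adipocyte and lipid droplet genes in every array by group, with bars for the mean and SD and open triangles for the 4 ambient week 10 samples whose week is in doubt. The skeletal muscle mean was -2.07 in filtered air at week 10, 0.72 in ambient air at week 10 and 1.09 in filtered air at week 16.

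The second question was how the lung differed between ambient and filtered air after 10 weeks. The week of 4 of the 7 ambient samples is in doubt. Without those 4, and so with fewer samples, most of the genes called at week 10 were no longer called. Genes of fast skeletal muscle were far higher in ambient air (n = 7) than in filtered air (n = 4). Acta1 (probe A_51_P246854), the actin of skeletal muscle, rose 25.6-fold (4.68 ± 0.76, adjusted p = 0.00699). Myh1 (probe A_51_P192042), a fast muscle myosin heavy chain, rose by 4.89 ± 0.72 (adjusted p = 0.0054), though its second probe differed by 0.36 and detection on 2 of 4 filtered arrays leaves its fold open. Plin4 (probe A_51_P495780) rose 4.18-fold (2.06 ± 0.39, adjusted p = 0.0223) and Dgat2 (probe A_51_P396003), an enzyme of triglyceride synthesis, 4.42-fold (2.14 ± 0.46, adjusted p = 0.0489). Btg2, an immediate early gene that slows cell division, fell by 0.89 ± 0.16 (adjusted p = 0.0186).

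In all, 33 genes rose and 5 fell, and 1561 had an unadjusted p under 0.05. The count rested on single samples, with between 6 and 62 genes when 1 was left out. Muscle genes filled most of the largest rises: Mylpf (4.82 ± 0.79), Myot (4.42 ± 0.89), Neb (4.41 ± 0.69), Myl1 (3.68 ± 0.62) and Myh4 had adjusted p from 0.00699 to 0.0308. Myot and Neb were detected on 2 of 4 filtered arrays, and Myh4 on 1 of 4, so no size is given for it. The others were Crct1 (4.14 ± 0.85) and Lor (3.45 ± 0.71), both from the cornified layer of squamous epithelium, and Ada (3.29 ± 0.64), an enzyme of purine breakdown, with adjusted p of 0.0365, 0.0367 and 0.0225. Besides Btg2, the falls were Arhgap22 (-0.91 ± 0.17, but 0.28 from the Cy5 channel alone), Fam133b (-0.82 ± 0.18), Snx18 (-0.65 ± 0.14) and Il1r1, the receptor of interleukin 1 (-0.65 ± 0.13), with adjusted p from 0.0225 to 0.0499.

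The skeletal muscle list rose by a median of 3.00 at week 10 (camera adjusted p = 2.38e-28; adjusted p = 0.0107 with an estimated correlation), with 8 of 18 genes called and 16 up and 1 down adjusted over the list alone. Its mean was higher in ambient air in all 4 batches, by 1.85 to 3.20, and its median was 2.61 without the 4 samples whose week is in doubt. The ambient sample was one of those 4 in 2 of the batches, and the other 2 batches gave 1.85 and 2.65. All 24 respiratory chain genes were higher, with a median of 0.74 (camera adjusted p = 1.81e-17; adjusted p = 0.113 with an estimated correlation) and 15 adjusted over the list alone. White adipocyte markers rose by a median of 0.92 (camera adjusted p = 1.18e-07; adjusted p = 0.0697 with an estimated correlation), with 1 gene called. Brown adipocyte markers rose by a median of 0.51 (camera adjusted p = 6.16e-05; adjusted p = 0.188 with an estimated correlation), with 2 called: Cox7a1, a muscle and brown fat subunit of the respiratory chain (1.85 ± 0.34, adjusted p = 0.0212), and Cpt1b (1.94 ± 0.41, adjusted p = 0.0432). The brown adipocyte median was 0.92 without the 4 samples whose week is in doubt and 0.31 with those 4 alone. Cardiac and smooth muscle markers rose by medians of 0.62 and 0.19 (adjusted p = 0.198 and 0.188 with an estimated correlation).

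The lipid droplet list, again not independent of these samples, rose by a median of 0.30 at week 10 (camera adjusted p = 3.37e-05; adjusted p = 0.188 with an estimated correlation). Of its 25 measured genes 18 were higher, 2 were called (Plin4 and Dgat2), and 6 rose and 1 fell adjusted over the list alone. Its median was 0.53 without the 4 samples whose week is in doubt, 0.19 with those 4 alone, and 0.47 without filtered sample 34. With the processing it ran from 0.17 with the filter on all 25 arrays and 0.19 with the coarser batch as a block to 0.47 with Signal Mean or without poor spots and 0.48 with the scanner gain. Cidec and Adipoq differed by 2.12 ± 0.52 (adjusted p = 0.0844) and 2.25 ± 0.56 (adjusted p = 0.0898), Cidea by 2.06 ± 0.73 (0.294), Plin1 by 0.97 ± 0.67 (0.682), Dgat1 by 0.29 ± 0.29 (0.811) and Ucp1 by 2.04 ± 1.08 (0.56). Plin2 differed by 0.01 ± 0.27 (adjusted p = 0.996). The droplet list mean was higher in ambient air in the 4 batches by 0.21 to 0.63 (0.55 and 0.47 in the 2 batches without the samples in doubt), on arrays where the white adipocyte mean was higher by 0.41 to 0.98 and the skeletal muscle mean by 1.85 to 3.20.

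Immediate early genes fell by a median of -0.39 (camera adjusted p = 9.48e-06; adjusted p = 0.0223 with an estimated correlation), with 13 of 17 lower, 1 called and 7 adjusted over the list alone. Nr4a1, an immediate early nuclear receptor, differed by -1.42 ± 0.33 (adjusted p = 0.0694) and Dusp1 by -0.86 ± 0.23 (0.128). B cell markers rose by a median of 0.49 (camera adjusted p = 0.000583; adjusted p = 0.198 with an estimated correlation), and their mean was higher in 3 of the 4 batches. Alveolar type 2 cell markers, from the cells that make surfactant, fell by a median of -0.32, with 15 of 17 lower (camera adjusted p = 0.00556; adjusted p = 0.323 with an estimated correlation); their surfactant gene Sftpc differed by -1.39 ± 0.79 (0.592). Fatty acid oxidation genes and proliferation genes rose by medians of 0.37 and 0.26 (adjusted p = 0.413 and 0.571 with an estimated correlation). Circadian clock genes rose by a median of 0.23 (camera adjusted p = 0.0366; adjusted p = 0.324 with an estimated correlation), which was 0.01 without the 4 samples whose week is in doubt, 0.39 with those 4 alone and 0.40 without ambient sample 45. Other medians that moved over 1.5 times were -0.22 for type 2 cells without filtered sample 38, and 0.29 for B cells and 0.30 for smooth muscle without filtered sample 40. Pollutant response genes were again not called: the median was 0.08 for aryl hydrocarbon receptor targets (camera adjusted p = 0.338), -0.02 for NRF2 targets (0.967) and 0.07 for inflammatory cytokines (0.672). Cyp1a1 differed by -0.62 ± 0.60 (0.804), Hmox1 by 0.02 ± 0.21 (0.987) and Saa3 by -0.34 ± 0.49 (0.889). Hmox1 was -0.78 and -1.01 in ambient samples 39 and 53, whose batch holds no filtered week 10 array. It lay between -1.69 and -1.44 in the other ambient samples, so its difference is not free of batch.

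Squamous epithelium markers had a median of 1.08 at week 10 with 25 of 28 higher and 3 called, against 0.23 for the 14 members not seen beforehand.

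Without the 4 samples whose week is in doubt 14 genes were called at week 10, 6 of them shared, and with the batch as a fixed block 22 were, 15 of them shared. Without the arrays that detected over 25% of negative controls, 0 genes were called by limma, 1299 had an unadjusted p under 0.05, and Acta1 differed by 4.44 ± 0.94 in place of 4.68 ± 0.76.

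**Figure D2:**
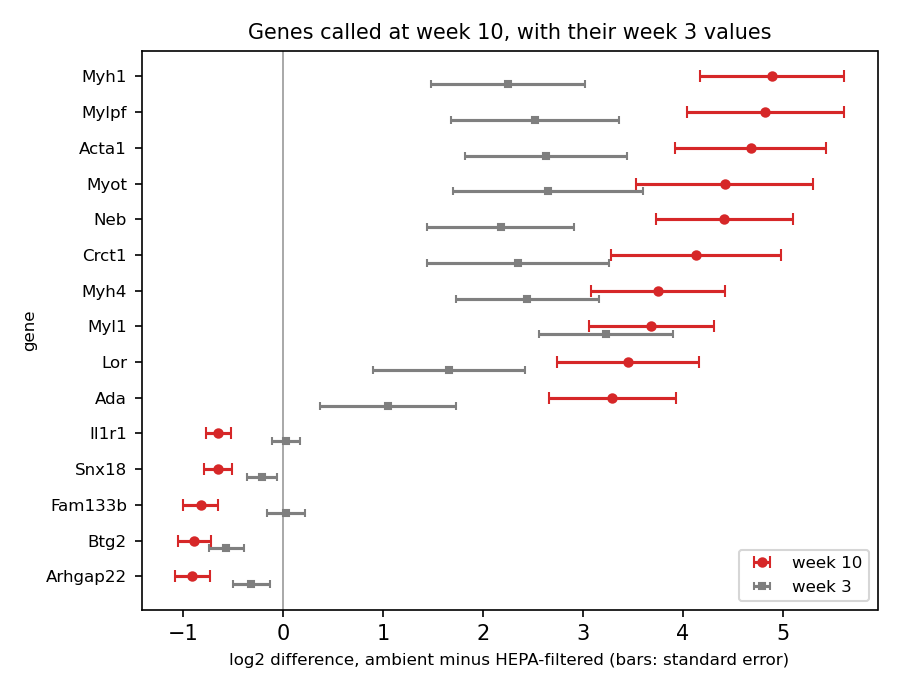
Log2 difference between ambient and filtered air at week 10, with its SE, for the 15 genes with the largest called rises and falls, beside the difference of the same genes at week 3. Fitted rises at week 10 ran from 3.29 for Ada to 4.89 for Myh1, with Myh1, Myot and Neb detected on 2 of 4 filtered arrays and Myh4 on 1 of 4, and falls from -0.91 for Arhgap22 (0.28 from the Cy5 channel alone) to -0.65 for Il1r1.

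Over weeks 3 and 10 together, the mean of both effects gave the average difference, which 1 of the weeks can carry alone. Acta1 rose 12.6-fold (3.65 ± 0.55, adjusted p = 0.0012) and Ucp1 by 3.54 ± 0.79 (adjusted p = 0.0173) in ambient air (12 samples against 8). Ucp1 was detected on 2 and 3 of 4 filtered arrays at weeks 3 and 10. At week 10 it was 5.99, 4.56, 0.22 and -0.20 in the filtered samples, against 2.88 to 5.79 in the ambient ones, so both kinds of air overlapped. The difference of Ucp1 was 5.04 at week 3 and 2.04 at week 10, and 1 gene was called in both separate weeks. Dgat2 and Plin4 rose 4.99-fold and 4.05-fold (2.32 ± 0.34 and 2.02 ± 0.28, adjusted p = 0.00108 and 0.000757), and the adipocyte genes Adipoq and Cidec 3.90-fold and 3.52-fold (adjusted p = 0.0111 for both). Dusp1, a phosphatase that ends MAP kinase signals, fell by 0.93 ± 0.17 and Nr4a1 by 1.18 ± 0.24 (adjusted p = 0.00381 and 0.01).

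This comparison called 293 rises and 40 falls, against 2108 genes at an unadjusted p under 0.05. Mylpf (3.67 ± 0.58), Myh1 (3.57 ± 0.53), Myot (3.53 ± 0.65), Myl1 (3.46 ± 0.46), Neb (3.30 ± 0.50), Crct1, Myh4 and Actn3 (2.96 ± 0.61), all but Crct1 genes of muscle, made up the rest of the largest rises, with adjusted p from 0.000634 to 0.0105. Crct1 was detected on 1 of 4 filtered arrays at week 3 and Myh4 on 1 of 4 at each week, so no size is given for them. Aldh1a2, which makes retinoic acid, fell by 1.18 ± 0.27, and Dgkh, Lrrc6 and Ccdc96 by 1.10 ± 0.27, 1.04 ± 0.25 and 0.96 ± 0.19, with adjusted p from 0.00725 to 0.0342. Atp13a4, Spink4 and Sox11 fell by 0.94 ± 0.25, 0.92 ± 0.24 and 0.86 ± 0.22, and Piwil2, detected on 1 of 4 filtered arrays at each week, was called lower, with adjusted p from 0.0378 to 0.0472.

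Of the 18 skeletal muscle genes 16 rose in the mean of both weeks (list median 2.45; adjusted p = 0.00827 with an estimated correlation), as did 12 of 24 respiratory chain genes (median 0.72; adjusted p = 0.0377). These included Sdhb (1.26 ± 0.26) and Uqcrc1 (0.89 ± 0.18). Adipocyte lists followed, with 7 of 19 brown (median 0.79; adjusted p = 0.00827) and 6 of 16 white markers called (median 1.01; adjusted p = 0.00827). Similarly, 4 of 19 cardiac markers were called (median 1.07; adjusted p = 0.0441), all of these p with an estimated correlation. The lipid droplet list, not independent of these samples, had 21 of 25 genes higher, 6 called, 11 up and 1 down adjusted over the list alone, and a median of 0.41 (camera adjusted p = 9.34e-09; adjusted p = 0.0441 with an estimated correlation). That median was 0.26 with the filter on all 25 arrays, 0.62 from Cy5 alone and 0.63 with Signal Mean. Its called members included Cidea (2.05 ± 0.54), Agpat2 (1.37 ± 0.32) and Lpin1 (0.79 ± 0.18), while Plin1, Plin2 and Dgat1 differed by 1.60 ± 0.49, 0.18 ± 0.20 and 0.40 ± 0.21 without being called. Of 22 fatty acid oxidation genes 5 rose, with Cpt1b at 2.12 ± 0.30, and of 18 fatty acid synthesis genes 3 rose, with Acacb at 1.58 ± 0.27 and Elovl6 at 1.83 ± 0.45 (adjusted p = 0.113 and 0.274 for the lists with an estimated correlation). Immediate early genes fell by a median of -0.43 (adjusted p = 0.00827 with an estimated correlation), with 6 of 17 called, Jun (-0.49 ± 0.11) and Btg2 (-0.73 ± 0.12) among them. B cell markers rose by a median of 0.53 (adjusted p = 0.0677 with an estimated correlation), with 2 called, Ms4a1 (0.94 ± 0.22) and Pou2af1 (1.07 ± 0.24). Camera also called rises of smooth muscle and proliferation genes (medians 0.33 and 0.19; adjusted p = 0.135 and 0.666 with an estimated correlation). Ciliated cell, interferon and neutrophil genes fell by camera (medians -0.27, -0.12 and -0.38; adjusted p = 0.556, 0.433 and 0.382 with an estimated correlation). Medians that moved over 1.5 times were -0.29 for immediate early genes without filtered sample 34, -0.05 for interferon without filtered sample 38, and 0.30, 0.08 and 0.29 for proliferation without filtered sample 6 or ambient samples 1 or 5. Squamous epithelium markers had a median of 1.14 with 14 of 28 called, against 0.24 for the 14 members not seen beforehand. Cyp1a1, Hmox1 and Saa3 differed by -0.78 ± 0.44, -0.08 ± 0.15 and -0.25 ± 0.36 (adjusted p = 0.468, 0.89 and 0.834).

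The count over both weeks was 218 without the 4 samples whose week is in doubt, with 181 genes shared, and 129 without the arrays that detected over 25% of negative controls, with 118 shared. Across the 15841 genes, which are not independent replicates, the effects at weeks 3 and 10 had a Pearson r of 0.456 and a Spearman rho of 0.292. The week 3 effect had a similar r of 0.446 and rho of 0.313 with week 16 over week 10 in filtered air. That comparison holds no ambient samples, so a likeness of this size is not particular to ambient air.

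Whether the effect of ambient air differed between weeks 10 and 3 was tested as the difference of both effects. Acute phase genes, secreted by liver and lung in inflammation, were lower in that difference by a median of -0.56 (camera adjusted p = 0.00295; adjusted p = 0.0209 with an estimated correlation), with 14 of 16 lower. The median was -0.37 without ambient sample 7 and -0.32 without filtered sample 34. Haptoglobin (Hp) differed by -1.89 ± 0.72 and was not called. Within the separate weeks this list was not called, with medians of 0.22 at week 3 (camera adjusted p = 0.0601) and -0.26 at week 10 (0.0741).

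No gene was called for this difference, 0 in limma against 540 with an unadjusted p under 0.05. Those 540 are a share under 0.05 of the 15841 genes tested, so fewer than chance alone gives on average. The smallest p was that of Dcpp2 (adjusted p = 0.919). Among the next were the prothrombin gene F2 (-1.82 ± 0.48), Hmgcs1 of cholesterol synthesis (-0.84 ± 0.23) and Il1r1 (-0.68 ± 0.19). No size is given for Dcpp2, Fat3, Glb1l3, Kirrel, Olfr1353 and Olfm2, each detected on at most 1 array of at least 1 group. By camera, cholesterol synthesis genes (median -0.27), brown adipocyte markers (-0.50) and alveolar type 2 cell markers (-0.37) were lower at week 10 than at week 3 in this difference, and heat shock genes (0.27) and skeletal muscle markers (0.68) higher. The skeletal muscle median was 0.30 without the 4 samples whose week is in doubt, 0.14 without filtered sample 2, 1.02 without filtered sample 4 and 0.31 without ambient sample 5. Cholesterol synthesis had -0.17 without filtered sample 2, and brown adipocytes -0.32 without ambient sample 7. Type 2 cells had -0.23, -0.58 and -0.24 without filtered sample 6, ambient sample 1 or filtered sample 40. Heat shock genes had 0.11, 0.17, 0.41 and 0.17 without filtered samples 10, 34 or 42 or ambient sample 57. Those 5 calls were lost with an estimated correlation (adjusted p = 0.665, 0.665, 0.874, 0.874 and 0.909). Without the 4 samples whose week is in doubt, 1 gene was called.

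At week 16, after recovery, 1 ambient sample stood against 4 filtered ones, so the spread between exposed mice at that time is unknown and each SE and p borrows the spread of the other groups. That ambient array detected 29.0% of negative controls, and limma on the week 16 arrays alone called 0 genes, with 1034 at an unadjusted p under 0.05. Ighg3 (probe A_51_P290619), an antibody heavy chain of plasma cells, was higher in that sample (5.14 ± 0.54, adjusted p = 2.91e-05), at 5.24 against 0.10 (SD 0.56), with detection on 2 of 4 filtered arrays. Vsig4, a complement receptor of resident macrophages, and Selp, the adhesion molecule P-selectin, were higher 5.01-fold and 3.50-fold (2.32 ± 0.42 and 1.81 ± 0.32, adjusted p = 0.0347 and 0.0344). Cyp2b10, a club cell enzyme that oxidises foreign compounds, was lower (-2.96 ± 0.50, adjusted p = 0.0304). Clic6, a chloride channel protein, was also called lower (adjusted p = 0.0347), but it was detected on 1 of 4 filtered arrays and differed by 0.12 from the Cy5 channel alone, so no size is given.

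With 1 further clone these were the 3 genes called higher and 3 called lower at week 16, while 1074 genes had an unadjusted p under 0.05. B cell markers were higher by a median of 0.74 in that sample, with 15 of 16 higher (camera adjusted p = 0.00174; adjusted p = 0.796 with an estimated correlation); Ighm differed by 2.48 ± 0.96. Endothelial markers (median 0.74) and heat shock genes (0.66) were higher by camera, each with an adjusted p of 0.796 with an estimated correlation. The lipid droplet and skeletal muscle lists were not called, with medians of 0.08 and 0.36 (camera adjusted p = 0.557 and 0.868), and the skeletal muscle median turned to -0.93 over the 7 genes left by the filter on all 25 arrays. None of Plin1 (0.09 ± 1.19), Plin2 (0.08 ± 0.48), Plin4 (0.07 ± 0.69), Cidea (-1.11 ± 1.30), Cidec (1.17 ± 0.92), Dgat1 (-0.24 ± 0.51, detected on 1 of 4 filtered arrays), Dgat2 (-0.11 ± 0.82), Adipoq (1.25 ± 1.00) and Ucp1 (-3.18 ± 1.92) was called. Cyp1a1, Hmox1 and Saa3 differed by 2.32 ± 1.07, -0.11 ± 0.37 and 1.82 ± 0.88 (adjusted p = 0.706, 0.986 and 0.729). With the batch as a fixed block 2 genes were called.

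Within filtered air, week 10 over week 3 gave the changes over time without ambient air. Heat shock genes, which keep proteins folded, fell as a group by a median of -0.36, with 15 of 17 lower (camera adjusted p = 5.41e-05; adjusted p = 0.37 with an estimated correlation). Fibroblast markers and extracellular matrix genes fell by medians of -0.35 and -0.33 (camera adjusted p = 0.000519 for both; adjusted p = 0.37 with an estimated correlation), with 16 of 18 and 22 of 26 lower. Skeletal muscle markers fell by a median of -0.69 and cholesterol synthesis genes rose by 0.16 (adjusted p = 0.998 and 0.71 with an estimated correlation). The skeletal muscle median was -0.11 without filtered week 3 sample 2 and -1.08 without filtered sample 4, and that of cholesterol synthesis 0.26 without filtered samples 4 or 40.

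Limma called 0 genes between these groups of 4 and 4, against 1044 with an unadjusted p under 0.05. Array weights called 2. The genes with the smallest p were Irf7, a master regulator of interferon (1.17 ± 0.20), and Cirbp, an RNA-binding protein induced by cold (1.45 ± 0.26), both at an adjusted p of 0.107. Npr3 (-1.89 ± 0.41) followed at 0.364, as did Dcpp2, Hemgn and Kirrel, each detected on 1 of 4 arrays at week 10, then Lama4 (-2.86 ± 0.64), Spata24 (0.75 ± 0.17), H2ac18 (0.80 ± 0.18) and Tcim (-0.86 ± 0.20). The chaperones Hspd1 and Hspa8 differed by -1.36 ± 0.38 and -0.83 ± 0.31, and Cyp1a1 by -2.24 ± 0.68 (adjusted p = 0.604). Droplet genes differed little: Plin4 by 0.39 ± 0.44, Dgat2 by 0.48 ± 0.52 and Plin2 by -0.02 ± 0.30, and the lipid droplet list had a median of 0.05 (camera adjusted p = 0.996).

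Also within filtered air, week 16 over week 10 covered time and the move from the shed to the animal facility, with 4 samples each. Its filtered week 10 samples were also the baseline of the week 10 effect of ambient air. Genes that rose or fell in both are therefore not independent support. Muscle genes rose in mice that had breathed filtered air: Acta1 54.8-fold (5.78 ± 0.85), Mylpf 47.2-fold (5.56 ± 0.89) and Myh1 by 5.39 ± 0.81, all at an adjusted p of 0.00357, though Myh1 was detected on 2 of 4 week 10 arrays and its second probe differed by 0.65. Lor and Crct1 of cornified epithelium rose 33.3-fold and 31.6-fold (5.06 ± 0.80 and 4.98 ± 0.96, adjusted p = 0.00357 and 0.0167). Dbp, a clock output gene, rose 7.29-fold (2.87 ± 0.52, adjusted p = 0.0126), from -1.09 (SD 0.54) to 1.78 (SD 0.20). Acoxl, Fam81a and Arhgap22 fell by 1.78 ± 0.33, 1.73 ± 0.33 and 1.26 ± 0.20 (adjusted p = 0.0129, 0.0146 and 0.00357), though Arhgap22 differed by 0.05 from the Cy5 channel alone. Macf1, which links actin and microtubules, and Bcl6b fell by 1.11 ± 0.20 and 1.08 ± 0.23 (adjusted p = 0.0124 and 0.0355).

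In all 45 genes rose and 10 fell, with 1779 at an unadjusted p under 0.05. The skeletal muscle list rose by a median of 3.26 (camera adjusted p = 1.96e-26; adjusted p = 0.0151 with an estimated correlation), with 9 of 18 called and 17 adjusted over the list alone. The 2 batches that held both times gave differences of 2.92 and 3.13 in its mean. All 24 respiratory chain genes were higher (median 0.63; adjusted p = 0.208 with an estimated correlation). Circadian clock genes rose by a median of 0.81 (camera adjusted p = 8.73e-05; adjusted p = 0.0824 with an estimated correlation), with 1 called and 9 up and 3 down adjusted over the list alone; Per2, Nr1d1 and Nr1d2 differed by 2.31 ± 0.61, 1.38 ± 0.37 and 1.34 ± 0.30. Immediate early genes fell by a median of -0.24 (adjusted p = 0.0824 with an estimated correlation), Btg2 by 0.85 ± 0.18. The lipid droplet list rose by a median of 0.22, with 18 of 25 higher and 0 called (camera adjusted p = 0.0327; adjusted p = 0.498 with an estimated correlation), in the direction of the adipocyte and muscle markers. White and brown adipocyte and cardiac muscle markers rose by medians of 0.78, 0.34 and 0.63 (adjusted p = 0.248, 0.464 and 0.248 with an estimated correlation). Fatty acid oxidation, proliferation and smooth muscle genes rose by medians of 0.39, 0.33 and 0.26 and cholesterol synthesis genes fell by -0.17 (adjusted p = 0.468, 0.6, 0.379 and 0.468 with an estimated correlation). With the batch as a fixed block 6 of the 12 list calls of this comparison were left, without the lipid droplet list, whose median was then 0.03.

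Within this comparison, single samples moved several list medians over 1.5 times. Lipid droplet genes had 0.40 and 0.42 without samples 34 or 58, and cholesterol synthesis -0.07 without sample 34. Immediate early genes had -0.46, -0.56, -0.59 and -0.39 without samples 40, 42, 50 or 58. Brown adipocytes had 0.22, 0.12 and 0.57 without samples 42, 54 or 58, and proliferation 0.21 and 0.19 without samples 46 or 50. Smooth muscle had 0.50, 0.43, 0.13, 0.48 and 0.41 without samples 34, 38, 42, 50 or 58.

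Squamous epithelium markers had a median of 1.54 with 6 of 28 called, against 0.09 for the 14 members not seen beforehand. Droplet genes from week 10 to week 16 in filtered air had these values: Plin4 1.81 ± 0.44, Dgat2 1.99 ± 0.52, Plin1 1.84 ± 0.75, Cidec 1.63 ± 0.58, Cidea 2.12 ± 0.83, Adipoq 1.36 ± 0.63, Dgat1 0.22 ± 0.33 (detected on 1 of 4 arrays at week 16) and Plin2 -0.35 ± 0.30, none called. Without the arrays that detected over 25% of negative controls limma called 0 genes, with 1704 at an unadjusted p under 0.05, and Acta1 differed by 5.78 ± 1.06. Across genes the week 3 effect of ambient air had a Pearson r of 0.446 and a Spearman rho of 0.313 with this difference, with which it shares no samples.

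**Figure D3:**
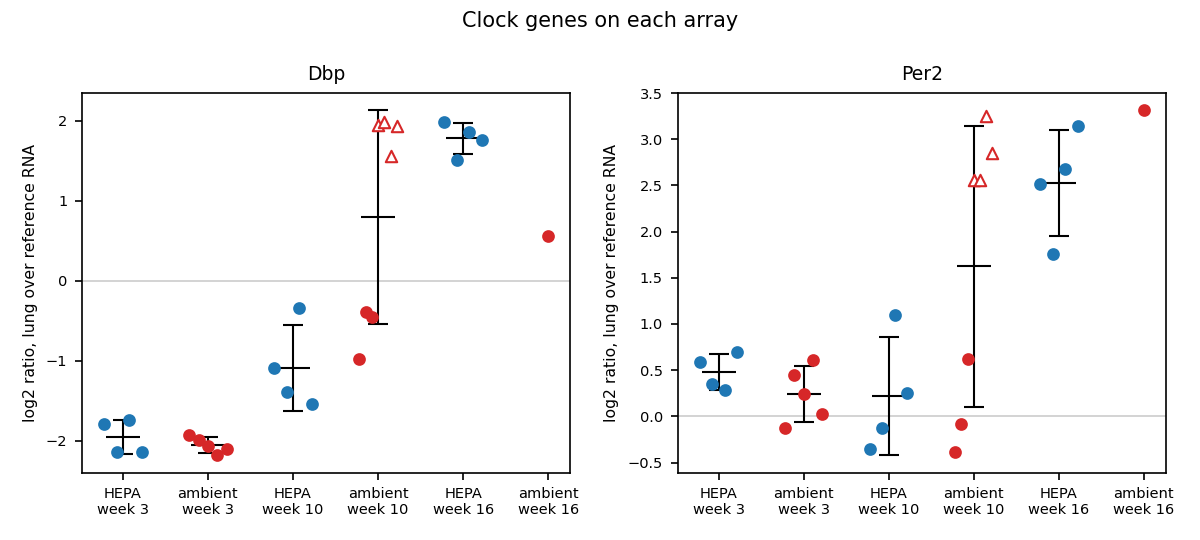
Log2 ratio of lung over reference for the clock genes Dbp and Per2 in every array by group, with open triangles for the 4 ambient week 10 samples whose week is in doubt. Dbp averaged -1.09 in filtered air at week 10, 0.80 (SD 1.34) in ambient air at week 10 and 1.78 in filtered air at week 16.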

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

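The tests of the clock genes, of skeletal muscle alone and jointly with squamous genes, of background, of batch and of adipocytes were chosen only after the result was seen. The squamous list was also written after the data were seen.

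Of 130 pairs of a group and a measure, 8 held a sample far from the others, and chance gives about 1 in 20 groups. Filtered week 10 sample 42 had 72.22% of negative controls detected, against 0% to 4.938% in the others. Ambient week 10 sample 45 had a squamous list mean of -0.6981, against 0.2675 to 0.8287. Ambient week 3 sample 7 had a brown adipocyte list mean of 1.309, against 0.225 to 0.4938. The lipid droplet list mean of filtered week 3 sample 6 was -0.1456, against -0.5297 to -0.4663. Plin1 was 4.124 in filtered week 16 sample 54, against 2.807 to 2.97, and Cidec was 5.942 in filtered week 16 sample 46, against 4.062 to 4.173. Plin4 was 2.614 in ambient week 10 sample 35, against 3.865 to 4.79, and Adipoq was 5.793 in ambient week 10 sample 37, against 4.344 to 4.903.

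The effect of ambient air differed between weeks 10 and 3 for 6 gene lists by camera, with a median difference of -0.5598 for acute phase genes, -0.3681 for alveolar type 2 cell markers, -0.5043 for brown adipocyte markers, -0.2741 for cholesterol synthesis genes, 0.2685 for heat shock genes and 0.6804 for skeletal muscle markers. Without the 4 samples in doubt the median was 0.30 for skeletal muscle and -0.42 for brown adipocyte markers. Each of the 6 moved over 1.5 times with some single sample left out, skeletal muscle to 0.14 without filtered week 3 sample 2, whose header names another sample. Of these, the acute phase list alone was also called with an estimated correlation (adjusted p = 0.0209). No gene was called by limma, with 540 at an unadjusted p under 0.05, fewer than chance alone gives on average.

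The 4 ambient week 10 samples numbered above the others of that week may carry a wrong week: with them that group holds 7 where the design text gives 5, and their numbers alternate with those of filtered week 16. Placed between filtered week 10 (0) and filtered week 16 (1) on the 12 clock genes that differ between those groups, the 4 averaged 0.773, the ambient week 16 sample lay at 0.999 and the other 3 ambient week 10 samples averaged 0.126, so the 4 lay 0.6469 above the 3. The planned axis of 55 called genes gave a difference of 0.0202, which speaks against a wrong week, but it also separated ambient week 3 (0.584) from filtered week 3 (0.136), so it did not measure week. Clock genes also follow the hour of collection, which is not given, so a different hour stays open for these genes, but it accounts for neither the numbers nor the group size. At week 3, ambient and filtered samples averaged -0.164 and -0.070 on the clock axis, so no rise in ambient air was seen there. An effect of ambient air on the clock in part of the week 10 mice remains open and untested.

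Genes of muscle and fat were higher in ambient air at weeks 3 and 10, with squamous genes listed after they had been seen to differ, whose 14 unseen fellows had medians of 0.12 and 0.23. The week 10 calls of white and brown adipocyte markers were lost with an estimated correlation (adjusted p = 0.0697 and 0.188). As the whole cause at week 3, the batch is argued against by the skeletal muscle list. Its mean was higher in ambient air in each of the 4 batches with both kinds of air (0.45 to 3.56). Its median was 2.12 with the batch as a fixed block, against 2.20 without. The mean within-batch difference was 0.8088 of the pooled median, but that share decides little. Those batches hold every week 3 array but ambient sample 7, and the share sets list means beside a median over genes. Unspecific background is argued against for the size of the difference, since the week 10 median without 5 arrays was 1.042 of the full one, but the calls of that week ended: Acta1 went from 25.6-fold (4.68 ± 0.76, adjusted p = 0.00699) to 21.7-fold (4.44 ± 0.94, adjusted p = 0.155), with fewer arrays and a larger SE. A response of the lung to ambient air, or to the housing that went with it, remains open and untested. Tissue next to the lung carried with the section also stays a candidate explanation. The skeletal muscle list rose in filtered air from week 10 to 16 too, by 1.477 of its week 3 difference. A joint test with the squamous members not seen beforehand (0.7485) rests on medians near 0 and decides nothing.

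Lipid droplet genes were higher in ambient air over weeks 3 and 10 by a median of 0.41, which ran from 0.26 with the filter on all 25 arrays to 0.63 with Signal Mean. With the mean of 31 adipocyte markers as a covariate the median became -0.04, a share of -0.08858 of its former value. That covariate differs between the groups as well, and it includes Cpt1b and Cox7a1, which muscle also expresses. The drop goes with adipocytes in the section but cannot tell them from muscle or from the air itself. For droplets formed in lung cells, the 21 droplet genes in no adipocyte or muscle list had a median of 0.3112, with 17 higher and 3 called (Agpat2, Dgat2 and Lpin1). Plin2 differed by 0.18 ± 0.20 (adjusted p = 0.771). Absence from those lists does not show that a gene is not expressed in fat or muscle, so that median decides nothing. These cannot be told apart here, because adipocyte markers and droplet genes rose in the same group.

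Chance could not be excluded for the 2 genes of week 3, since 7 of 100 splits of those samples gave as many genes and the highest other gave 73. That split exchanged ambient sample 5 and filtered sample 2, whose skeletal muscle list means were -1.28 and 0.23. With so many more genes than the real split it points to a structure of the samples, whose cause was not tested. For week 10 the splits argue against chance, with 38 genes against 7 in the highest other split (1 of 100 as large). They also do for the mean over both weeks, with 333 against 3 (1 of 100). The same holds for week 16 over 10 in filtered air, with 55 against 1 (1 of 35). These splits used all arrays and were not repeated without the samples in doubt or the arrays with many negative controls detected. The week 10 count itself fell as low as 0 under other settings and 6 with 1 sample left out. For the difference of the effects and for week 10 over 3 in filtered air 0 genes were called, against 1 in the highest other split of each, so every split gave as many (100 of 100 and 35 of 35) and the splits say nothing about chance there.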

How the results depend on the processing

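The alternatives with batch, Signal Mean, poor spots and negative controls were tests chosen only after the result was seen. Counts of genes in the order given in the report were 2 for week 3, 38 for week 10, 333 for the mean of both, 0 for the difference of both, 6 for week 16, 0 for week 10 over 3 and 55 for week 16 over 10 in filtered air. Outside single samples, they stayed within 1.5 times of these under 7 of 19, 14 of 20, 16 of 19, 18 of 19, 8 of 18, 18 of 19 and 15 of 19 alternatives, and Aquantile scaling moved nothing because it leaves log ratios as they are. Where no cause is given below, the cause was not tested. Precision was limited by the number of arrays and by signal over background.

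Week 3 gave 9 genes without background subtraction, 1 with an offset of 16, 16 from Cy5 alone, 18 with the filter on all 25 arrays (6070 genes tested), 1 with all probes apart, 0 with the scanner gain as a covariate, 1 with trend and robust, 7 with array weights and 0 from its own arrays. It gave 10 with batch as a random block, 0 with the coarser batch as a block, and 1 without arrays with over 25% of negative controls. Week 10 gave 66 with the filter on all 25 arrays, 71 with array weights, and 14 without the 4 samples in doubt (fewer samples). It gave 22 with batch and 15 with the coarser batch as a fixed block, and 0 without arrays with over 25% of negative controls (1299 at an unadjusted p under 0.05 in limma). Week 16 gave 15 without background subtraction, 2 from Cy5 alone, 16 from the series matrix, 3 with the filter on all 25 arrays, and 3 with the scanner gain. It gave 0 from its own arrays, 2 with either batch as a fixed block, 12 with Signal Mean and 1 without poor spots. Without arrays with over 25% of negative controls it gave no value, because its ambient array is among them.

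The mean over both weeks gave 161 from Cy5 alone, 218 without the 4 samples in doubt and 129 without arrays with over 25% of negative controls, with 119, 181 and 118 genes shared. The difference of both effects gave 1 without the 4 samples in doubt, and week 10 over 3 in filtered air gave 2 with array weights. Week 16 over 10 in filtered air gave 91 from Cy5 alone, 115 with the filter on all 25 arrays, 34 with the scanner gain, and 0 without arrays with over 25% of negative controls (1704 at an unadjusted p under 0.05). An unadjusted p under 0.05 with at least a 1.5-fold change gave 915 for week 3, 866 for week 10, 1047 for week 16, 749 for the mean, 473 for the difference, 698 for week 10 over 3 and 1225 for week 16 over 10. Gene list calls went from 68 to 15 with an estimated correlation, to 28 with fry and to 65 with batch as a fixed block, which took week 16 over 10 from 12 to 6.

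With each sample left out in turn, the counts ran from 0 to 34 at week 3, 6 to 62 at week 10, 3 to 7 at week 16, 169 to 387 for the mean, 0 to 0 for the difference, 0 to 0 for week 10 over 3 and 30 to 44 for week 16 over 10. At week 3 the count was 34 without filtered sample 2, 0 without filtered 4 or 10 or ambient 3 or 7, 21 without ambient 1, 24 without ambient 5 and 1 without ambient 9. At week 10 it was 12, 6, 17 and 9 without filtered 34, 38, 40 and 42, 24 without ambient 39, 62 without ambient 45, and 18 without ambient 49 or 53. At week 16 it was 3 without filtered 46, 50 or 54. For the mean it was 169, 176, 217, 196 and 219 without filtered 4, filtered 10, ambient 7, filtered 40 and filtered 42. For week 16 over 10 it was 35, 36, 30 and 31 without filtered 34, 46, 50 and 58.

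From Cy5 alone, without the reference channel, Arhgap22 turned to 0.275889 at week 10 and to 0.0500167 for week 16 over 10, and Clic6 turned to 0.124489 at week 16. Neb and Lrrc6 had no value with the filter on all 25 arrays, which left them out. Other values of called named genes kept their direction, 3002 with their call and 641 without it. Medians of lists that were not called turned in places: at week 16 skeletal muscle went from 0.36 to -0.93 with the filter on all 25 arrays (7 genes left), and from Cy5 alone circadian clock from -0.13 to 0.30 and white adipocytes from 0.24 to -0.08. Without its genes that are also adipocyte markers, the lipid droplet list had a camera adjusted p of 4.18e-05 at week 3, 0.00773 at week 10 and 4.57e-05 for the mean, and its call for week 16 over 10 was lost (0.389). A slide as a block was not run because the files give no slide. No paired analysis was possible because the groups share no replicate numbers, and the batches read from file headers, which put 1 array of each kind together in 4 batches each at weeks 3 and 10, served as a block instead.

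Among 9 lists followed through the settings, medians of called ones that moved over 1.5 times kept their direction. With the filter on all 25 arrays, which left fewer genes, immediate early genes had -0.58 at week 3, -0.74 at week 10 and -0.85 for week 16 over 10, B cells 1.01 and 0.77 at weeks 3 and 10 and 0.89 for the mean, and brown adipocytes 1.20 at week 10, 1.43 for the mean and 1.21 for week 16 over 10. White adipocytes had 1.67 for the mean, and circadian clock 0.96 at week 10 and 1.59 for week 16 over 10. From Cy5 alone the respiratory chain had 0.45 at week 10 and for the mean, and skeletal muscle 1.30 for the difference of both effects. At week 10 circadian clock had 0.15 with the scanner gain, 0.40 with batch and 0.38 with the coarser batch. For week 16 over 10, brown adipocytes had 0.83 from Cy5 alone, 0.59 with array weights and 0.22 without poor spots. Lipid droplet genes had 0.07 from Cy5 alone, 0.14 with the filter on all 25 arrays, 0.44 with the scanner gain and 0.03 with batch there. Immediate early genes had -0.54 from Cy5 alone, -0.47 with batch and -0.70 without arrays with over 25% of negative controls there.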

Other observations

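The test of the clock genes by sample was chosen only after the result was seen. Genes of the circadian clock differed among the ambient week 10 samples. Per2, a core clock repressor, averaged 2.80 in samples 45, 49, 53 and 57 and 0.05 in the other 3, against 0.22 in filtered week 10 and 2.53 in filtered week 16. Dbp averaged 1.85 and -0.61 in those ambient samples, against -1.09 and 1.78 in the filtered ones. At week 3 Dbp was close in both kinds of air, at -2.05 (SD 0.10) in ambient and -1.96 (SD 0.22) in filtered samples.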
